A study of Rattus norvegicus with 48 samples.

How the data were processed

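Hepatic miRNA was measured in 48 livers of male Fischer F344 rats given 0, 50, 500 or 1000 ppm phenobarbital in the diet for 1, 3, 7 or 14 days, in 16 groups of 3 animals. Per the labels' protocols, total RNA was extracted from frozen liver with Trizol, checked on a bioanalyser, and labelled with Cy3 using an Agilent kit. Each sample was hybridised to 1 array of Agilent's rat miRNA design 019159, and the 48 arrays lay on 6 slides of 8, scanned on 1 date.

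Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 9.5.1.1, and the probe coordinates in them are on the rat build rn4. They hold linear intensity values per spot, of which the processed signal is already background-subtracted and can be negative. Each array held 7000 miRNA spots for 938 probes and 350 miRNAs, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. A second deposited table per array gives the total intensity and a detected flag per miRNA, per the file headers. The deposited series table holds log2 values for 95 miRNAs. Set against each array's own totals, its values equalled log2 of the total signal, raised to at least 1, minus a constant per array, to within 1.6e-06. The constant lay at the 75.07 percentile of the 373 rows of that array's table in all 48 arrays, so scale, direction and centring of the series table are known. Its column medians ran from 1.78 to 2.40.

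For the values reported, spots flagged as outliers were left out and the processed signals of each probe's spots were averaged. Probe means were summed over a miRNA's probes and divided by the array's 75th percentile, taken over the 75 probes with at least 50% of spots well above background on every array. A common floor of -4.55 on the log2 scale, the median over arrays of the lowest signal of a detected miRNA, was then set and log2 taken. The floor held 3.19% of the tested values. Where a group had a miRNA well above background on no array, the fold is given as at least the brighter group's mean over the mean, in the dimmer group, of the higher per array of the miRNA's own signal and the lowest probe well above background. This bound concerns dim signal alone and leaves out the spread between animals. The 83 miRNAs detected on all 3 arrays of at least 1 group were tested, 50 of which were detected on all 48 arrays.

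No array had a saturated spot, and flagged spots made up 1.51 to 8.33% of an array. The scaling percentile ran from 351 to 3473 intensity units with a median of 775, and the number of arrays limits the precision. The median half-width of the 95% interval of a change was 0.35 on the log2 scale for 1 day and 0.18 for the mean of 4 days.

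Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group, a spread shared by all 16 groups and 32 residual degrees of freedom. Adjusted p is limma's p after Benjamini-Hochberg adjustment over the 83 miRNAs, with a threshold of 0.05. Each dose was set against the controls of the same day, and the differences were also averaged over the 4 days. Doses were compared with each other, a linear trend over the 4 dose ranks was fitted, and F tests asked whether the 1000 ppm effect and the control animals differed between days. No method of testing is given in the sources used here.

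Fixed lists of 20 miRNA families, clusters and cell type markers were matched by name, any arm counting as a member. The 9 lists with at least 3 measured members were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry. Named miRNAs are those past the threshold, up to 15 in each direction at 1000 ppm, 10 for the other means, trend and dose differences, and 5 for single days (10 smallest p in F tests), plus measured list members and the 5 brightest. These rules, the tests and all but 3 alternatives were fixed before the data were examined. Of the uncalled list members that the rule allows, those named in the text were chosen after their values were seen.

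On simulated arrays with the real spread, limma recovered 59.4% of 1.2-fold and 94% of 1.5-fold changes in the 1000 ppm mean of 4 days among 83 miRNAs, 21 of which were changed at once. For 1000 ppm on day 14 it recovered 15.1% of 1.2-fold, 64% of 1.5-fold and 89.4% of 2-fold changes. The simulated miRNAs varied independently and had no floor. Adjustment is stricter when fewer miRNAs change, so recovery of a few changes can be lower.

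The alternatives were the percentile over all probes, quantile normalization, normexp background correction with an offset of 50, the deposited totals, the series table, no filter, only miRNAs detected on every array, slide or replicate number as a block, dose in ppm for the trend, and each array left out. Array brightness as a covariate, a higher floor of -2.60, and leaving out the 4 arrays with fewer than 65 detected miRNAs were added after the results were seen. No pair of arrays was a duplicate, the closest pair differing by 0.145 (root mean square, log2).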

Results

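The liver miRNA profile was measured after dietary phenobarbital, a barbiturate that induces drug-metabolising enzymes and enlarges the rat liver. Male Fischer F344 rats, an inbred strain, received 0, 50, 500 or 1000 ppm for 1, 3, 7 or 14 days, with 3 animals in each of the 16 groups. The arrays detected between 57 and 107 miRNAs each, with a median of 80. miR-122, the dominant hepatocyte miRNA, was the brightest of all, at 6.23 ± 0.20 on the scaled log2 scale (SD, n = 48). miR-21, let-7f, miR-22 and let-7a followed by summed signal. Mean detected miRNAs per array were 77.2 in controls, 77.9 at 50 ppm, 81.8 at 500 ppm and 84.7 at 1000 ppm, with SDs of 11.8, 13.4, 9.05 and 9.78 (n = 12 each). Array brightness, the mean scaling percentile on the log2 scale, was 9.44, 9.55, 9.57 and 9.85 in that order (SD 0.54, 0.50, 0.38 and 0.68). A difference between doses in either was not tested.

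The first question was which miRNAs differed at the highest dose when all 4 days were averaged. miR-29c, a family member known for targeting collagen transcripts, rose 1.18-fold at 1000 ppm (log2 0.24, SE 0.055, n = 12 against 12, adjusted p = 0.0115). It was above the same-day control mean in 11 of 12 animals. miR-365 rose 1.17-fold (log2 0.23, SE 0.063, adjusted p = 0.0294), with 10 of 12 animals above the control mean. These were the 2 miRNAs of 83 past the threshold at this dose, both higher, with 18 at an unadjusted p under 0.05. The probes for miR-29c lie on chromosome 13 at 110968101 to 110968122 and those for miR-365 on chromosome 10 at 65915003 to 65915023 (rn4). Blocking on slide gave 0.23 for each, and within the 6 slides miR-29c differed by 0.11 to 0.34 and miR-365 by 0.0078 to 0.39. Without the 4 arrays with the fewest miRNAs the changes were 0.20 and 0.21 and both calls ended (adjusted p = 0.0903 for each, with a range over 12 alternatives of 0.00534 to 0.242 for miR-29c and 0.0147 to 0.803 for miR-365). The percentile over all probes (0.47 for each), normexp (0.18 and 0.14) and the series table (0.26 for each) also ended both calls, and quantile normalization and no filter ended that of miR-365. Leaving out single arrays ended no miR-29c call, and ended the miR-365 call for 10 of 24 arrays, with adjusted p between 0.0524 and 0.101. Those were control replicate 2 of day 1, replicates 1 and 3 of day 3, 2 and 3 of day 7 and 1 of day 14, and 1000 ppm replicate 1 of day 1, 3 of day 3, 2 of day 7 and 1 of day 14.

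Of the miR-29 family, 1 of 3 measured members passed over all miRNAs at 1000 ppm and 3 when adjusted over the list alone. miR-29a was 0.15 higher (SE 0.061, adjusted p = 0.176) and miR-29b 0.25 higher (SE 0.11, adjusted p = 0.176), or -0.027 with normexp, neither past the threshold. The list passed camera with the preset correlation (adjusted p = 0.00761) and fry, which does not compare it with other miRNAs (adjusted p = 0.00121), and gave an adjusted p = 0.0627 in camera with an estimated correlation. At 500 ppm it did not pass camera (adjusted p = 0.171, and adjusted p = 0.4 with an estimated correlation) but passed fry (adjusted p = 0.0237). At 1000 ppm on day 14 its median was -0.011, with 1 of 3 members above 0 (camera, adjusted p = 0.33, and fry, adjusted p = 0.542). None of the other 8 tested lists passed at 1000 ppm with camera, the smallest adjusted p being 0.215, for the stellate, fibroblast and smooth muscle markers, or with fry, the smallest being 0.199. The miR-200 family, with 2 measured members, had 0 past the threshold and 2 adjusted over the list alone: miR-200b was 0.40 (SE 0.14) and miR-200a 0.31 (SE 0.14), or -0.12 and -0.16 with normexp. Both entered the tested set through dosed groups, since neither was detected on all 3 arrays of any control group. Of the Dlk1-Dio3 cluster, miR-494 alone was measured, at -0.70 (SE 0.33, adjusted p = 0.217), and of the miR-34 family miR-34a alone, at -0.056 (SE 0.13). The stellate markers had 0 of 3 members past the threshold, with miR-199a-5p at -0.23 (SE 0.10) and miR-143 at -0.12 (SE 0.11); with the percentile over all probes these became 0.0017 and 0.12. Among 5 hepatocyte-enriched members 0 passed, with miR-122 at -0.16 (SE 0.079, adjusted p = 0.22) and miR-192 at -0.0044 (SE 0.067, adjusted p = 0.959). With the percentile over all probes, which moved the median of all miRNAs to 0.23, they were 0.072 and 0.23. Of 4 leukocyte markers 0 passed, with miR-223 at -0.14 (SE 0.078), or 0.094 with the percentile over all probes. The let-7, miR-30, miR-15/16, miR-23/27/24 and miR-17 cluster lists had 0 members past the threshold out of 8, 6, 5, 5 and 6, or 1, 0, 0, 0 and 0 when adjusted over the list alone. Endothelial and erythroid markers had 0 of 2 and 0 of 1, and the miR-183 cluster, miR-221 with miR-222, miR-181 family, striated muscle, neural and pancreas lists had 0 members in the tested set.

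At 500 ppm, over the 4 days, the same 2 miRNAs rose. miR-365 was 1.19-fold higher (log2 0.25, SE 0.063) and miR-29c 1.16-fold higher (log2 0.21, SE 0.055), each with adjusted p = 0.0215 and above the control mean in 12 of 12 animals. miR-29a was 0.19 higher (SE 0.061, adjusted p = 0.0831). The 4 leukocyte markers had a median change of -0.14, passing fry (adjusted p = 0.0366) but not camera (adjusted p = 0.0751, or 0.127 with an estimated correlation), with 0 members past the threshold. At an unadjusted p under 0.05 there were 17 miRNAs. Within the 6 slides miR-29c differed from controls by 0.041 to 0.42, higher on all 6, and miR-365 by -0.089 to 0.50, higher on 5. Blocking on slide, 13 were called, these 2 among them, and without the 4 arrays with the fewest miRNAs limma called 0, with 16 at an unadjusted p under 0.05. Both calls also ended with the percentile over all probes, quantile normalization, normexp, the series table and no filter. Leaving out control replicate 2 of day 1, control replicate 1 of day 3, or 500 ppm replicate 1 or 3 of day 7 also gave 0; without 500 ppm replicate 2 of day 3 it was 1, without control replicate 1 or 3 of day 1 it was 4, and without 500 ppm replicate 2 of day 7 it was 5.

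The changes at 500 and 1000 ppm share their control arrays. Across the 83 miRNAs they correlated at 0.655, against 0.484 for simulated unchanged groups, with a covariance of 0.0205 against 0.00704. With the controls divided by replicate number the covariance was 0.00667 to 0.0196. Both called lists held the same 2 miRNAs, where independent lists would share 0.0482 and simulated unchanged groups shared 0. Neither value measures agreement, since the first leaves out the shared controls and unchanged groups give few calls.

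At 50 ppm, miR-494, a member of the imprinted Dlk1-Dio3 cluster on chromosome 6, was lower over the 4 days. It fell by 1.25 on the log2 scale (SE 0.33, n = 12 against 12, adjusted p = 0.0472) and was below the control mean in 10 of 12 animals. By day it was 2.68, 1.59, 0.42 and 0.31 lower (SE 0.66 each), and on day 1, when controls were at 1.84, it was also 1.48 and 2.07 lower at 500 and 1000 ppm (adjusted p = 0.528 and adjusted p = 0.0806). It was the only one of 83 past the threshold, with 10 at an unadjusted p under 0.05. The call ended with a replicate block (adjusted p = 0.0668), quantile normalization, normexp, no filter and without the 4 arrays with the fewest miRNAs (adjusted p = 0.0706, 0.126, 0.336 and 0.331). It also ended without any 1 of 18 of the 24 arrays, with adjusted p up to 0.168. The exceptions were control replicates 1 of day 1, 2 of day 3 and 1 of day 7, and 50 ppm replicates 2 of day 3, 2 of day 7 and 3 of day 14.

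Across the dose ranks, the linear fit rose for 4 miRNAs and fell for 1, though none of the 5 moved the same way at every step. Mean levels at 0, 50, 500 and 1000 ppm were 0.072, 0.040, 0.283 and 0.308 for miR-29c and -0.859, -0.743, -0.610 and -0.627 for miR-365. They were 1.337, 1.278, 1.524 and 1.482 for miR-29a, -3.822, -3.820, -3.534 and -3.611 for miR-22*, and -2.609, -2.569, -2.667 and -2.846 for let-7e. Fitted slopes follow. miR-29c rose by 0.095 per dose step (log2, SE 0.017, adjusted p = 0.000335), miR-365 by 0.083 (SE 0.020, adjusted p = 0.00732), miR-29a by 0.068 (SE 0.019, adjusted p = 0.0344) and miR-22* by 0.092 (SE 0.028, adjusted p = 0.04). let-7e fell by 0.081 on the log2 scale per step (SE 0.025, adjusted p = 0.04), but was 0.0020 with the percentile over all probes, which moved the median of all miRNAs to 0.23 at 1000 ppm, and miR-22* was -0.011 with normexp. The miR-29 list passed camera for the trend (adjusted p = 0.00489, adjusted p = 0.0472 with an estimated correlation) and fry (adjusted p = 8.66e-05), with 2 of 3 members past the threshold both over all miRNAs and adjusted over the list alone. The miR-29c and miR-365 calls held with any of the 48 arrays left out. The calls of miR-29a, miR-22* and let-7e ended for 9, 18 and 19 arrays. The count was 2 without control replicate 1 of day 3 or 1 or 2 of day 14, or 1000 ppm replicate 1 of day 7 or 1 or 2 of day 14. It was 3 without control replicate 1 of day 7, 50 ppm replicate 1 of day 3, 500 ppm replicate 1 of day 1, 2 of day 3 or 1 of day 7, or 1000 ppm replicate 1 or 3 of day 1 or 2 or 3 of day 3, and without the 4 arrays with the fewest miRNAs 2 of the 5 were called. The percentile over all probes called 8 higher and 0 lower, array brightness 5 higher and 6 lower, and the series table called 1, none of the 5. Normexp called miR-29c alone, and no filter, the miRNAs detected on every array and the higher floor each called 3 higher and 0 lower.

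**Figure D1:**
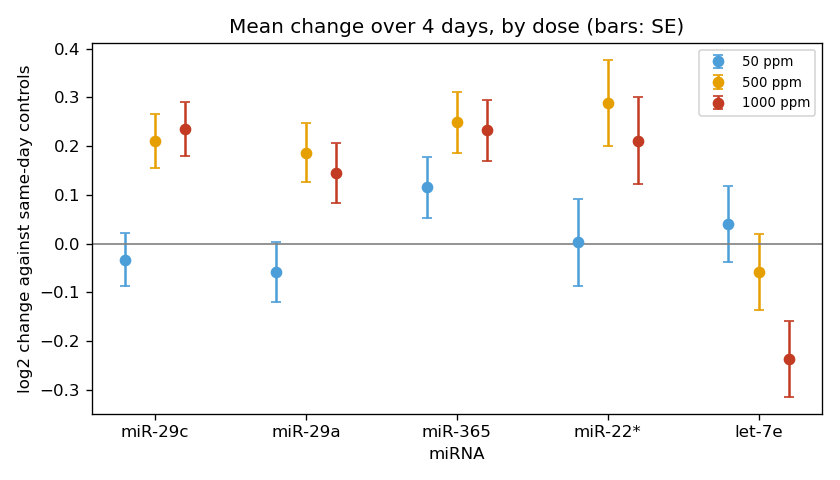
Mean log2 change against same-day controls over 4 days (vertical axis) for 5 miRNAs (horizontal axis), with 50, 500 and 1000 ppm as separate points and bars showing the SE. miR-29c stood at 0.21 and 0.24 at 500 and 1000 ppm, and let-7e at -0.24 at 1000 ppm, though with the percentile over all probes, which moved the median of all miRNAs to 0.23 at 1000 ppm, its trend was 0.0020.

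Doses were also compared directly. From 50 to 500 ppm, miR-29c (log2 0.24, SE 0.055, adjusted p = 0.00758), miR-29a (0.25, SE 0.061, adjusted p = 0.01), miR-31 (0.33, SE 0.088, adjusted p = 0.0147) and miR-22* (0.29, SE 0.089, adjusted p = 0.0367) were higher. miR-10a-5p fell by 0.26 on the log2 scale (SE 0.065, adjusted p = 0.01), and miR-142-3p, a leukocyte marker detected on 9 and 7 of 12 arrays at the 2 doses, fell by 0.44 (SE 0.13, adjusted p = 0.0354). All 6 calls ended with the series table, where 0 passed (11 at an unadjusted p under 0.05), and with the percentile over all probes, where 1 other miRNA passed. The miR-142-3p call ended for 12 and the miR-22* call for 13 of 24 left-out arrays, and leaving out 500 ppm replicate 3 of day 7 reduced the 6 calls to 3. Normexp kept miR-29c and miR-29a alone, and no filter kept miR-29c, miR-29a and miR-10a-5p. From 500 to 1000 ppm, 1 miRNA passed: miR-333 fell by 0.65 (SE 0.17, adjusted p = 0.039), with 8 at an unadjusted p under 0.05. That call ended in 9 of 11 alternatives that measured it, slide as a block among them (adjusted p = 0.1), and was kept with a replicate block and without the 4 arrays with the fewest miRNAs. It also ended for 17 of 24 left-out arrays, the exceptions being 500 ppm replicates 1 of day 3, 2 of day 7 and 3 of day 14, and 1000 ppm replicates 2 and 3 of day 3, 2 of day 7 and 2 of day 14.

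On single days, the smallest adjusted p was that of miR-200b, a regulator of the epithelial state, after 14 days of 1000 ppm. Its level was -2.59 ± 0.11 at 1000 ppm and -4.09 ± 0.31 in controls (SD, n = 3 each), at least 2.65-fold higher (adjusted p = 0.000562). It was well above background on 3 of 3 treated arrays and 0 of 3 control arrays, and detected on 3 and 1. miR-200a, from the same cluster on chromosome 5, was at least 1.505-fold higher (adjusted p = 0.28), not well above background on any of the 3 control arrays, or -0.12 (log2) with normexp, so 1 of the 2 measured members of the miR-200 family passed, or 2 when adjusted over the list alone. At 500 ppm on day 14 miR-200b was at least 1.62-fold higher (adjusted p = 0.138), or -0.21 (log2) with normexp. These least folds bound dim signal alone and leave out the spread between animals, so smaller changes are possible. At 1000 ppm limma's 95% interval ran from 1.89-fold to 4.20-fold for miR-200b and from 1.14-fold to 2.52-fold for miR-200a. At 500 ppm it ran from 1.16-fold to 2.58-fold for miR-200b. On the same day at 1000 ppm the stellate, fibroblast and smooth muscle markers had a median change of -0.38 with 0 of 3 above 0 (camera, adjusted p = 0.0859, or 0.438 with an estimated correlation), and the leukocyte markers one of -0.25 with 0 of 4 above 0 (adjusted p = 0.139, or 0.386). With slide as a block the 1000 ppm change of miR-200b was 1.49, and on the 1 slide with both groups it was 1.57 for 2 arrays against 1. With normexp it was 0.096 (adjusted p = 0.892) and with the higher floor 0.046 (adjusted p = 0.083), against 0.000215 to 0.00903 in the other 9 alternatives that measured it.

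**Figure D2:**
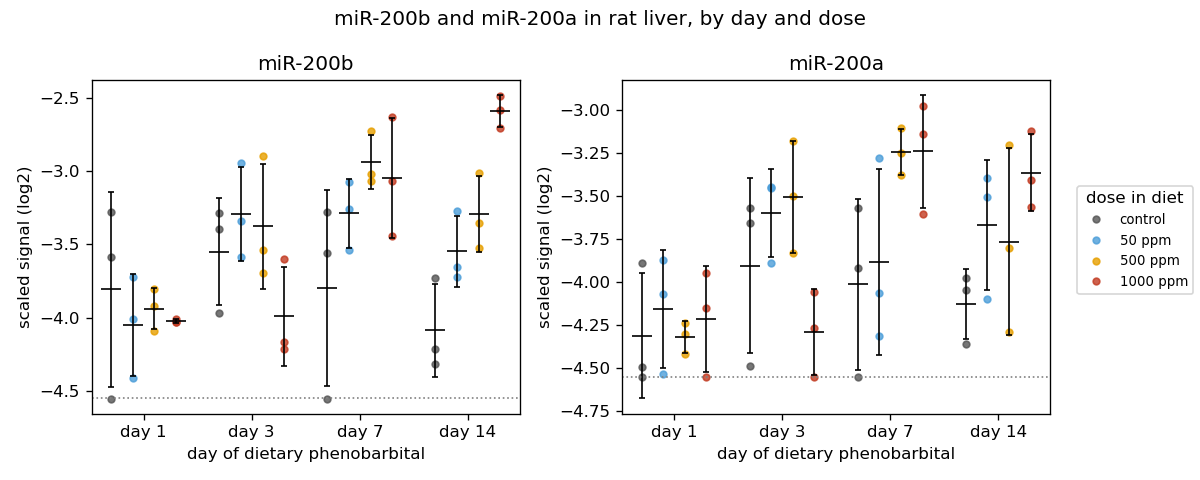
Scaled log2 signal (vertical axis) of miR-200b and miR-200a by day (horizontal axis) and dose; each point is 1 animal, black marks are means ± SD of 3 animals, and the dotted line is the floor of -4.55. At day 14 miR-200b lay at -2.59 at 1000 ppm and -4.09 in controls.

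The effect of 1000 ppm on miR-200b differed between the days (F = 10.04, adjusted p = 0.00537), the 1 miRNA of 83 to do so, with 9 at an unadjusted p under 0.05. Its mean at 1000 ppm was -4.02 on day 1, -3.99 on day 3, -3.05 on day 7 and -2.59 on day 14, against -3.81, -3.55, -3.80 and -4.09 in controls. In the same order it was well above background on 0, 1, 2 and 3 of 3 arrays at 1000 ppm and 1, 1, 0 and 0 in controls. Several of these means therefore rest on dim signal. In 14 of 100 regroupings of the arrays at least 1 miRNA was called, so chance cannot be excluded for this count. The call ended with the percentile over all probes (adjusted p = 0.197), normexp (adjusted p = 0.44) and the higher floor (adjusted p = 0.398). Without 1000 ppm replicate 2 of day 3 or control replicate 1 of day 7, 2 were called.

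At 50 ppm on day 1, 5 miRNAs differed from controls. miR-92a was higher (log2 1.00, SE 0.24, adjusted p = 0.00715), miR-497 1.39-fold higher (log2 0.47, SE 0.11, adjusted p = 0.00715) and miR-196c 3.05-fold higher (log2 1.61, SE 0.49, adjusted p = 0.0366). miR-494 fell by 2.68 on the log2 scale (SE 0.66, adjusted p = 0.00715). miR-17-5p was at least 1.16-fold higher in controls (adjusted p = 0.016), well above background on 1 of 3 control arrays and 0 of 3 treated ones, and 1 of its 2 probes showed the difference. Without 50 ppm replicate 3 the count was 0, and without replicate 1 or 2 it was 8 or 9; miR-17-5p also lost its call without control replicate 3, miR-196c without control replicate 1 (0.86) and miR-494 without control replicate 2. With the percentile over all probes, or with normexp, miR-494 alone was called, and normexp put miR-497 at -0.077. Slide as a block ended the calls of miR-17-5p (adjusted p = 0.0599) and miR-196c (adjusted p = 0.094), as did no filter and the higher floor, the series table ended those of miR-92a, miR-497 and miR-196c, and quantile normalization that of miR-497. Daily means of later controls ran from -0.79 to -0.48 for miR-494, -0.80 to -0.45 for miR-92a, -4.33 to -4.10 for miR-17-5p and -1.83 to -1.47 for miR-497. Day-1 controls were at 1.84, -1.46, -3.54 and -1.93 in that order, and 50 ppm animals at -0.84, -0.46, -4.225 and -1.46. These differences cannot be told apart from a shift of the day-1 controls.

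At 500 ppm on day 7, miR-139-3p was higher (adjusted p = 0.00235), the 1 miRNA past the threshold, at -3.86 ± 0.60 against -4.55 in controls (SD, n = 3 each). All 3 control values and 1 treated value lay at the floor, so the size of the difference is set by the floor. Over the 4 days all 12 controls lay there (SD 0), which narrows the shared spread behind limma's p. With 1 array left out, limma's adjusted p ran from 7.99e-11 to 0.125, so it cannot be taken at face value. miR-139-3p was well above background on 1 of 3 arrays in each group, 1 of its 2 probes showed the rise, and normexp gave -0.041 (log2). The percentile over all probes, the series table and the higher floor also ended the call. The call ended without 500 ppm replicate 1 or 3, and 2 were called without control replicate 3 or 500 ppm replicate 2. In the other 9 single-day comparisons 0 of 83 miRNAs passed limma's threshold. At an unadjusted p under 0.05 there were 8, 0 and 5 at 50 ppm on days 3, 7 and 14, then 6, 3 and 12 at 500 ppm on days 1, 3 and 14, and 10, 7 and 12 at 1000 ppm on days 1, 3 and 7. Leaving out control replicate 2 of day 3 gave 6 calls at 50 ppm, and 1 call each came at 50 ppm on day 14 without 50 ppm replicate 3, at 500 ppm on day 14 without control replicate 2, and at 1000 ppm on day 7 without 1000 ppm replicate 3. Blocking on slide gave 5 calls at 500 ppm on day 14. miR-29b and miR-29c stood 0.68 (SE 0.21) and 0.34 (SE 0.11) above controls at 1000 ppm on day 1, each with adjusted p = 0.0806; with normexp miR-29b was -0.35. On day 14 they were -0.41 (SE 0.21, adjusted p = 0.503) and -0.011 (SE 0.11, adjusted p = 0.954).

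Control animals also differed between days, in 7 miRNAs, with 18 at an unadjusted p under 0.05. miR-494 was 1.84 ± 1.10 on day 1 and -0.79 ± 0.23 on day 14 (SD, n = 3 each, adjusted p = 0.0229). miR-92a was -1.46 ± 0.090 on day 1 and -0.69 ± 0.31 on day 14 (adjusted p = 0.0229). miR-17-5p, miR-497 and miR-99a had the same adjusted p, miR-93 had 0.0257 and miR-333 0.0414. Of these 7, 4 were among the 5 miRNAs called at 50 ppm on day 1, a comparison that uses the same day-1 controls. With slide as a block, without control replicate 2 or 3 of day 1, without replicate 3 of day 7 or without replicate 1 of day 14, 4 were called. The percentile over all probes and quantile normalization each called 1 of the 7. The series table called 2, 1 of them among the 7, and no filter called 1 that was not; normexp called 0 (2 at an unadjusted p under 0.05).

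**Figure D3:**
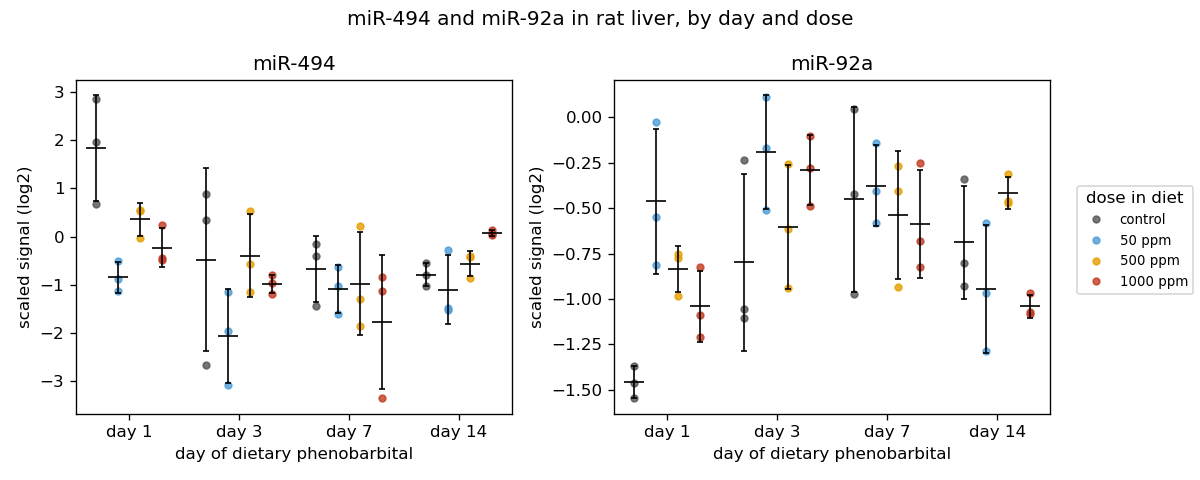
Scaled log2 signal (vertical axis) of miR-494 and miR-92a by day (horizontal axis) and dose; each point is 1 animal and black marks are means ± SD of 3 animals. In day-1 controls miR-494 averaged 1.84 and miR-92a -1.46.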

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

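The tests of explanations below were chosen after the results were seen; the counts of regroupings were planned. The effect of 1000 ppm on miR-200b differed between days (adjusted p = 0.00537), from a change of -0.44 (log2, SE 0.28) on day 3 to at least 2.65-fold higher on day 14. That fold bounds dim signal alone, and limma's 95% interval on day 14 ran from 1.89-fold to 4.20-fold. A difference between slides stays open: with slide as a block the day-14 change was 1.49 (SE 0.29), but miR-200b was well above background on 0 of 3 control arrays. Signal from the near-identical miR-200c is argued against by miR-200c being detected on 0 of the 3 treated arrays. A larger share of bile duct or other epithelial cells stays open too: miR-200b rose by 0.73 (SE 0.24) more than miR-200a, but miR-200a lay near the floor. An effect of phenobarbital on miR-200b also stays open; the dimness of the miRNA in controls, where normexp gave a change of 0.096, leaves its size uncertain.

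The control animals differed between days in 7 miRNAs, of which miR-494 averaged 2.48 higher (log2) on day 1 than in the 9 later controls, while miR-93 differed by -0.071 and was lowest on day 14. With array brightness as a covariate all 7 miRNAs were still called, which argues against brightness as the whole source. A difference between slides stays open, since 4 of the 7 were still called with slide as a block. So do 1 odd array, since leaving out 1 control array kept 3 to 6 of the 7, and the scaling of the arrays, since each of 3 other scalings kept 1. Time on the diet is confounded with the day of the animals and was not tested.

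miR-29c and miR-365 were higher at 500 and 1000 ppm. Low values in the shared control arrays are argued against for miR-29c, which was 0.24 and 0.27 (SE 0.055 each) higher at 500 and 1000 than at 50 ppm, and narrowly for miR-365 at 500 ppm (0.13, SE 0.063), and stay open for miR-365 at 1000 ppm (0.12, SE 0.063). The scaling of the arrays as the whole source is argued against at 1000 ppm by the lowest changes over 3 other scalings, 0.26 (SE 0.096) and 0.25 (SE 0.074), though the miR-365 call ended in all 3 and the miR-29c call in 2, where the SE was larger. At 500 ppm it stays open, since the lowest changes were 0.14 (SE 0.096) and 0.18 (SE 0.097) against 0.21 (SE 0.055) and 0.25 (SE 0.063), and both calls ended in all 3. The 4 arrays with the fewest miRNAs as the whole source are argued against, since without them miR-29c was 0.17 and 0.20 (SE 0.057 each) and miR-365 0.22 and 0.21 (SE 0.062 each) at 500 and 1000 ppm, though all 4 calls ended. Those arrays were control replicates 2 of day 1 and 1 of day 3, and 50 ppm replicates 1 of day 3 and 3 of day 14. The comparisons with 50 ppm above therefore do not set their dimness aside.

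Outside the 83 tested miRNAs, 31 were detected on at least 1 of the 36 treated arrays and on none of the 12 control arrays, and 3 on control arrays alone. Of the 31, 21 were detected on a single array, and 14 were detected on the brightest array, 1000 ppm replicate 3 of day 7.

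Regroupings of the same arrays were used to ask whether chance can be excluded for each count. For the dose trend, 1 of 100 regroupings reached the real count of 5 (highest other 2). For the control days it was 1 of 100 for 7 (highest other 4), for 500 ppm 1 of 100 for 2 (highest other 1), for 1000 ppm 3 of 100 for 2 (highest other 3), and for 500 against 50 ppm 2 of 100 for 6 (highest other 7). No allowance was made for the number of counts examined. Taken singly, these shares were under 0.05, which argues against chance for each count alone but does not exclude it. With 100 regroupings drawn, shares of 2 or 3 of 100 are imprecise. The counts for 500 ppm, 1000 ppm and the trend share their controls and all include miR-29c and miR-365. Chance stays open for 50 ppm (7 of 100 for 1, highest other 5) and for 1000 against 500 ppm (17 of 100 for 1, highest other 1). The same holds for the effect of 1000 ppm by day (14 of 100 for 1, highest other 5). The regroupings that called 5 for a real count of 1 may reflect a structure of the samples, which was not tested. The 12 single-day comparisons have 10 splits each, too few for a share under 0.05. There the real counts were 5 at 50 ppm on day 1 (reached by 1 split, highest other 3), 1 at 500 ppm on day 7 (4 splits, highest other 1) and 1 at 1000 ppm on day 14 (1 split, highest other 0). For the 9 counts of 0, reached by all 10 splits, the highest other was 3 at 50 ppm on day 3, 1 at 1000 ppm on day 7 and 0 elsewhere.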

How the results depend on the processing

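Array brightness as a covariate, the higher floor and the fits without the 4 arrays with the fewest miRNAs were chosen after the results were seen. Of 687 fits of 59 named results under the alternatives, 513 kept direction and side of the threshold, 146 lost the call, 6 gained one and 22 reversed. The 59 include results not called in the main fit, which count among the 513 when they stayed uncalled with the same sign. The 513 therefore do not measure how often a call held, and only called results could lose one. The miR-29c trend passed in 12 of 13 alternatives, the series table giving adjusted p = 0.0524. Signal over background limits miR-200a, miR-200b, miR-17-5p and miR-139-3p, which lay near the floor. The normexp setting adds 50 to each spot, which compresses such dim miRNAs. Whether that accounts for the calls lost and the changes reversed with normexp was not tested. Some fits also used smaller sets of miRNAs or arrays, and the cause of the other differences was not tested.

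Counts that changed by over 1.5 times follow, with the count at an unadjusted p under 0.05 in parentheses after each limma count of 0. With the percentile over all probes they were 1 at 50 ppm on day 1, 0 (2) at 500 ppm on day 7, 0 (4) for the 500 ppm mean, 0 (19) for the 1000 ppm mean, 1 for 500 over 50 ppm, 0 (11) for 1000 over 500 ppm, 8 for the trend, 0 (2) for the 1000 ppm effect by day and 1 for the control days. With normexp they were 1, 0 (2), 0 (5), 0 (1), 2, 0 (0), 1, 0 (3) and 0 (2) in that order, 0 (0) at 1000 ppm on day 14 and 0 (3) for the 50 ppm mean; it moved the median of all miRNAs by -0.12, -0.14 and -0.10 at 50, 500 and 1000 ppm. With quantile normalization they were 1 at 50 and 500 ppm on day 14 and at 1000 ppm on day 1, 0 (10) for the 50 ppm mean, 0 (18) for the 500 ppm mean, 1 for the 1000 ppm mean, 0 (6) for 1000 over 500 ppm and 1 for the control days. With the series table they were 0 (2) at 500 ppm on day 7, 2 at 1000 ppm on day 1, 1 for the 500 and 1000 ppm means, 0 (11) for 500 over 50 ppm, 0 (12) for 1000 over 500 ppm, 1 for the trend and 2 for the control days. The deposited totals gave 0 (8) for 1000 over 500 ppm.

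With no filter they were 2 at 50 ppm on day 14, 2 at 500 and 1 at 1000 ppm on day 1, 0 (17) for the 50 ppm mean, 0 (21) for the 500 ppm mean, 3 for 500 over 50 ppm, 0 (10) for 1000 over 500 ppm, 3 for the trend and 1 for the control days. With miRNAs detected on every array they were 0 (3) at 500 ppm on day 7, 1 at 500 ppm on day 14, 0 (4) at 1000 ppm on day 14, 0 (2) for 1000 over 500 ppm, 3 for the trend, 0 (6) for the effect by day and 4 for the control days. With slide as a block they were 3 at 50 ppm on day 1, 2 and 5 at 500 ppm on days 7 and 14, 2 for the 50 ppm mean, 13 for the 500 ppm mean, 0 (14) for 1000 over 500 ppm and 4 for the control days. Replicate numbers were not taken as pairs in the main fit. Deviations of same-numbered arrays from their group means correlated above 0.1 in 20 of 36 pairs and below -0.1 in 11 (median 0.158). The rule set for pairing, every pair above 0.1, was not met, but noisy true pairs could also miss it, so pairing stays open. The replicate block gave 0 (11) for the 50 ppm mean and changed no other count by over 1.5 times. With the higher floor they were 3 at 50 ppm on day 1, 1 on day 3, 0 (4) and 1 at 500 ppm on days 7 and 14, 0 (7) at 1000 ppm on day 14, 0 (5) for 1000 over 500 ppm, 3 for the trend, 0 (8) for the effect by day and 4 for the control days. With array brightness they were 1 at 50 ppm on day 3, 4 for the 500 ppm mean, 0 (6) for 1000 over 500 ppm and 11 for the trend. Without the 4 arrays with the fewest miRNAs they were 8 at 50 ppm on day 1, 1 at 500 ppm on day 14, 0 (6), 0 (16) and 0 (13) for the 3 means, 2 for the trend and 4 for the control days. With an estimated correlation 0 lists passed in place of 1 at 1000 ppm.

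With 1 array left out, with limma sharing the spread over groups, counts ran from 0 to 9, 0 to 6, 0 to 0 and 0 to 1 at 50 ppm on the 4 days, 0 to 0, 0 to 0, 0 to 2 and 0 to 1 at 500 ppm, and 0 to 0, 0 to 0, 0 to 1 and 1 to 1 at 1000 ppm. They ran from 0 to 2, 0 to 5 and 1 to 3 for the means at 50, 500 and 1000 ppm, 3 to 8 for 500 over 50 ppm, 0 to 2 for 1000 over 500 ppm, 2 to 7 for the trend, 1 to 2 for the effect by day and 4 to 7 for the control days.

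With normexp the 1000 ppm changes of miR-29c and miR-365 were 0.18 and 0.14 and both calls ended, and these reversed: miR-497 at 50 ppm on day 1 (-0.077), miR-139-3p at 500 ppm on day 7 (-0.041), miR-22* (-0.011), miR-200b (-0.028) and miR-29b (-0.013) in the trend, miR-200b (-0.12), miR-200a (-0.16) and miR-29b (-0.027) in the 1000 ppm mean, miR-200b (-0.14) and miR-200a (-0.17) in the 500 ppm mean, miR-29b at 1000 ppm on day 1 (-0.35), and on day 14 miR-200a at 1000 ppm (-0.12) and miR-200b at 500 ppm (-0.21). With the percentile over all probes these reversed: let-7e in the trend (0.0020), and in the 1000 ppm mean miR-122 (0.072), miR-199a-5p (0.0017), miR-143 (0.12), miR-223 (0.094) and miR-192 (0.23). miR-192, whose change was near 0, also reversed with the series table (0.023), slide as a block (0.0027) and array brightness (0.017), and ran from -0.027 to 0.022 with 1 array left out.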

Other observations

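All values here were chosen after the results were seen, and none is a test of an explanation. Measured epithelial and imprinted-cluster members were few. Of the 5 miR-200 family members on the array, miR-200c was detected on 1, miR-141 on 0 and miR-429 on 3 of 48 arrays. Of the miR-183 cluster, miR-96 was detected on 4 arrays, miR-182 on 1 and miR-183 on 0. miR-221 was detected on 22 arrays and miR-222 on 0, and miR-181a on 5. Of the 47 array miRNAs matched to the Dlk1-Dio3 list, 2 were detected on any array and miR-494 alone entered the tests.

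The miR-23/27/24 list, tested at 50 ppm in addition to the planned doses, had a median change of 0.15 over the 4 days (camera with the preset correlation, adjusted p = 0.00898, adjusted p = 0.477 with an estimated correlation, and fry, adjusted p = 0.0767), with 0 of 5 members past the threshold over all miRNAs and 2 adjusted over the list alone.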
